A study of Rattus norvegicus with 10 samples.

How the data were processed

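The data were 10 Affymetrix rat expression arrays, 1 for each of 10 male Lewis rats, an inbred strain, hybridised with RNA from the prefrontal cortex. The labels give each rat scores for acoustic startle, locomotion, sugar feeding and prepulse inhibition, and 7 of the rats a plus maze score. No unit is stated for any score. The labels give no treatment, so the rats form 1 group and each behaviour was treated as a number measured on every rat. No paired analysis was possible because each rat gave a single array and no rat was measured under a second condition.

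The deposited values are log2 expression summaries per probe set. Per the submitters' processing notes they were made with GCRMA under R 2.6.2. GCRMA corrects the background with probe sequence, normalises by quantiles and summarises the probes of each probe set. The GCRMA version is not given in the sources used here. The table held 31099 probe sets with values from 0.237 to 16.2, of which 57 were array controls. The number of arrays limits the precision of every slope.

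Probe sets were named from the platform annotation. A single gene symbol was given for 20826 of the 31042 probe sets that were not controls, several symbols for 436 and none for 9780. The gene numbers of 20758 matched the RefSeq annotation of the GRCr8 rat assembly, and 0 symbols changed. Controls were left out. The 50% of probe sets with the highest mean over all arrays were kept, which left 15521 with a mean log2 of at least 3.99. Of these, 11576 had 1 symbol, 273 several and 3672 none.

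For each behaviour a linear model of log2 value on the score, scaled to an SD of 1 over the rats in the fit, was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). Tests were two-sided, with Benjamini-Hochberg adjustment over 15521 probe sets and a threshold of 0.05. A slope is the log2 difference per SD of the score, given with its SE. The 4 main behaviours used 10 rats and the plus maze score 7. The fit was tested on simulated data with these scores: slopes of 0.4 were recovered in 86.6% to 89.6% of the altered probe sets for the 4 main behaviours, and in 67.2% for the plus maze score. Slopes of 0.2 were recovered in 40.3% to 46.3% and in 25.4%. The simulated noise was independent between probe sets, and slopes of 0.2, 0.4 and 0.8 were planted together, which eases the adjusted threshold. These shares therefore do not give the chance of finding a lone slope in the actual data, where probe sets vary together.

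The 28 gene lists comprised immediate-early genes, dopamine signalling, serotonin signalling, noradrenaline and acetylcholine receptors, glutamate receptors and transporters, GABA synthesis, receptors and transporters, interneuron markers and peptides, opioid and endocannabinoid genes, and feeding and metabolic peptides and receptors. Further lists were the glucocorticoid and stress response, the heat shock and unfolded protein response, circadian clock genes, schizophrenia and sensorimotor gating candidates, synaptic vesicle and release machinery, oxidative phosphorylation and cytosolic ribosomal proteins. The rest were markers of myelin and oligodendrocytes, oligodendrocyte precursors, astrocytes, microglia and macrophages, endothelium and pericytes, blood and red cells, choroid plexus and ependyma, meninges and fibroblasts, striatal projection neurons, the olfactory bulb, and superficial and deep layer excitatory neurons.

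Lists were tested on the probe set of highest mean for each of 8483 genes with limma's camera at a preset correlation of 0.01. Benjamini-Hochberg adjustment ran over 100 tests, 25 lists by 4 behaviours, and lists with fewer than 5 measured members were left out. Camera with an estimated correlation and limma's fry were run beside it. A list or marker score is the mean of the members' centred log2 values in a rat.

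The named genes followed a rule: in each direction the 8 probe sets of smallest p with 1 symbol past the threshold, or where a direction had none, the 5 of smallest unadjusted p in that direction. The rule asked for the same slope sign in every fit that left out 1 rat. It added the 3 members of smallest p of each list past the threshold, and a panel of genes, of which Fos, Egr1, Arc, Drd1, Drd2, Gad1, Pvalb, Grin2a, Htr2a, Nr3c1 and Crh are reported. For the plus maze score it took 3 genes per direction. Genes named outside the rule are said to have been chosen after their values were seen.

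Correlations across rats are Pearson's r and Spearman's rho with two-sided permutation tests, with 1e+05 resamples for 10 rats and exact enumeration for 7. Each r was recomputed without the 2 rats farthest from a median: that of the first-named score for pairs of behaviours, of the behaviour score for pairs with a component or a technical or marker measure, and of the first-named measure for the further pairs. Families held 10 pairs of behaviours, 12 pairs of a principal component and a behaviour, 20 pairs of a technical or marker measure and a behaviour, and 10 further pairs. Principal components were taken from the 15521 centred probe sets. The difference between the 3-prime and 5-prime probe sets of control genes was taken as a measure of RNA integrity, and the mean of 18 spike-in probe sets as the spike-in level.

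The alternatives were no filter or the upper 25% by mean, quantile normalization, centring of each array on its median, eBayes with trend and robust options, the unmoderated Pearson test, ranks of the scores, an adjusted p of 0.1, and 1 probe set per gene. Others were the 4 scores in 1 model, covariates for RNA integrity and for component 1, array weights, other summaries of the lists, unit variance for the components, and each rat left out in turn. These, the lists, the tests and the rule for named genes were fixed before the data were examined. Covariates for the striatal marker score and the spike-in level, the fit without 3 rats, and both scalings for the lists were added after seeing the data. An alternative count was taken as unchanged within 1.5 times the reported count, and a test result by its direction and its side of the threshold.

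The behaviour scores were also paired with the rats at random. With the actual pairing included, the tests were repeated on 100 pairings. Samples of other experiments were not analysed here. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.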

Results

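Expression was measured in the prefrontal cortex of 10 male Lewis rats, with 1 array per rat and 31042 probe sets after the array controls. The dissected piece comprised frontal areas Fr1 and Fr2 in front of bregma, without the olfactory bulb. The rats belonged to a set of 40 tested for behaviour, were killed 6 days after the last test, and were not treated. The series title gives the question as how brain mRNA levels relate to behaviour within an inbred strain. Rats are numbered 1 to 10 by replicate. The arrays had medians of 3.91 to 4.02 and upper quartiles of 8.13 to 8.25 (log2), and pairs of arrays correlated across probe sets at 0.985 to 0.996. Genes are not independent replicates in such a correlation. Array number limits the precision of the slopes, whose median SE was 0.043 to 0.044 log2 per SD for the 4 main scores and 0.051 for the plus maze score.

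Correlations between the behaviours, among them prepulse inhibition, the reduction of a startle by a weaker preceding sound, did not pass the adjusted threshold for any pair of scores. Startle averaged 682 with an SD of 208, locomotion 12756 with an SD of 2944, sugar feeding 1.25 with an SD of 0.72, and prepulse inhibition 27.3 with an SD of 12.6 (n = 10 each, units not stated). The plus maze score averaged 14.4 with an SD of 21.5 (n = 7). Sugar feeding and prepulse inhibition had r = -0.67 (permutation p = 0.0380) and rho = -0.56 (permutation p = 0.0956), and r was -0.71 without the 2 rats farthest from the median. Locomotion and sugar feeding had r = 0.63 (permutation p = 0.0536) and rho = 0.59 (permutation p = 0.0802), with r = 0.72 without 2 rats. Startle and locomotion had r = -0.63 (permutation p = 0.0533) and rho = -0.47 (permutation p = 0.177), with r = -0.49 without 2 rats. Over the 10 pairs tested, two-sided, the adjusted p of these was 0.179 for r and 0.47 for rho.

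Startle and prepulse inhibition had r = 0.45 (permutation p = 0.189, adjusted 0.378) and rho = 0.31 (permutation p = 0.388, adjusted 0.647), which rested on rats 1 and 2, since r was -0.36 without them. Sugar feeding and the plus maze score had r = -0.68 (exact p = 0.0734, adjusted 0.184) and rho = -0.58 (exact p = 0.187, adjusted 0.47) in 7 rats. That relation rested on rat 5, and r was -0.0016 without it. The 5 other pairs had adjusted p of at least 0.526 for r.

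**Figure D1:**
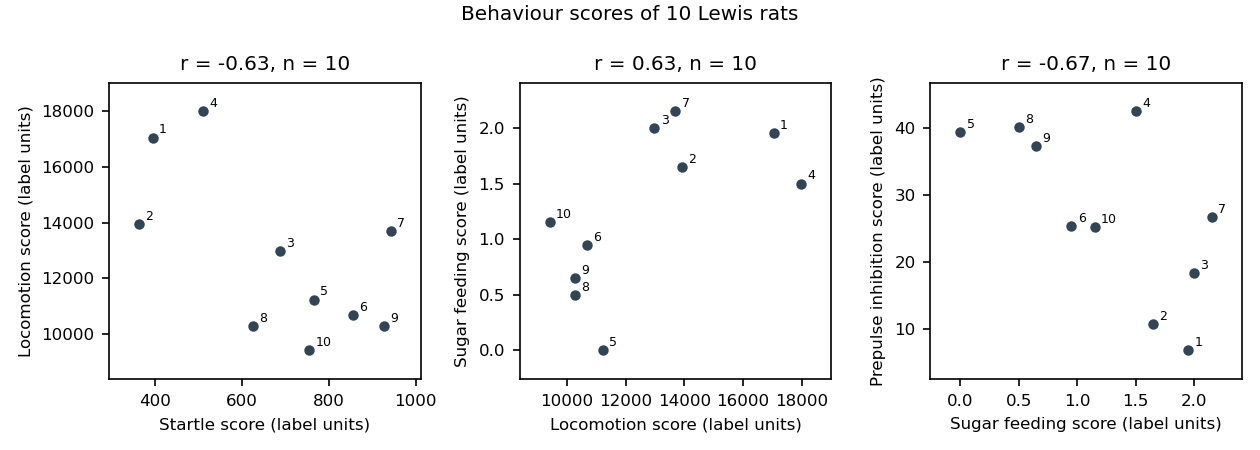
Each point is 1 rat, numbered by replicate, with its scores in the units of the labels, for the pairs startle and locomotion (r = -0.63), locomotion and sugar feeding (r = 0.63), and sugar feeding and prepulse inhibition (r = -0.67). Rats 1 and 2 had the lowest prepulse inhibition and the lowest startle scores, and no pair passed the adjusted threshold.

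Some genes of striatal projection neurons differed several-fold between rats, while Foxp1, Meis2, Foxp2 and Rasd2 spanned 1.41-fold to 2.30-fold. Rgs9 spanned 2.04-fold, but its lowest value, 4.03 log2, lay near the filter level, so its span may be cut short. Its highest values were in rats 7, 10 and 4, at 5.06, 4.32 and 4.32 log2. Drd1, the D1 dopamine receptor, spanned 14.0-fold between rats, from 5.79 to 9.60 log2 (mean 7.22, SD 1.41, n = 10). The enkephalin precursor gene Penk spanned 4.53-fold and Ppp1r1b, which encodes DARPP-32, 4.28-fold. Drd2 ran from 4.05 to 7.57 log2 and the retinoic acid receptor gene Rarb from 3.59 to 6.76, with their lowest values near or below the filter level of 3.99. Without rat 7 their highest values were 6.16 and 5.83. Rats 7, 4 and 10 held the highest values of the list, with scores of 1.20, 0.73 and 0.39 log2 above the mean of all rats. Myelin genes varied with them at smaller size: Mag spanned 2.44-fold, Mal 2.44-fold and Mbp, the myelin basic protein gene, 1.50-fold. Of the meningeal and fibroblast markers, the collagen genes Col1a2 and Col1a1 spanned 8.21-fold and 5.98-fold, with the highest values in rats 9 and 3. The score of the choroid plexus and ependymal list ran from -0.98 to 1.23 and was also highest in those rats. Its 2 measured members were Igf2 and Igfbp2. It therefore tells nothing of the other genes of that list and does not show choroid plexus or ependyma. Penk, Foxp1, Foxp2, Meis2, Rasd2, Mal, Mbp, Col1a1, Col1a2 and, on the first component, Pdyn were chosen after their values were seen.

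Across the 10 rats the striatal and myelin scores had r = 0.80 (permutation p = 0.00495, adjusted 0.0165 over 10 pairs) and rho = 0.92 (permutation p = 0.00049, adjusted 0.0049). Without the 2 farthest rats r was 0.64 (permutation p = 0.0855). The first principal component held 38.4% of the variance, the second 16.1% and the third 11.4%. Drd1, Drd2, Rarb, Penk, Ppp1r1b and Pdyn were among the genes at the positive end of the first, and 93% of the 200 probe sets at its negative end had no gene symbol, against 23.7% of all tested probe sets. The first component and the striatal score, which share probe sets, had r = 0.84 (permutation p = 0.00157, adjusted 0.00785 over 10 pairs) and rho = 0.84 (permutation p = 0.00359, adjusted 0.0120), with r = 0.79 without 2 rats. With the mean level of unnamed probe sets it had r = -0.89 (permutation p = 0.00039, adjusted 0.0039) and rho = -0.89 (permutation p = 0.00117, adjusted 0.00585), with r = -0.88 without 2 rats. The unnamed probe sets are also among those the component was taken from, so part of this correlation was built in. Of the 12 pairs of a component and a behaviour, the first component and prepulse inhibition came closest, with r = 0.57 (permutation p = 0.0912, adjusted 0.642) and rho = 0.64 (permutation p = 0.0543, adjusted 0.652). That r was 0.28 without rats 1 and 4.

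**Figure D2:**
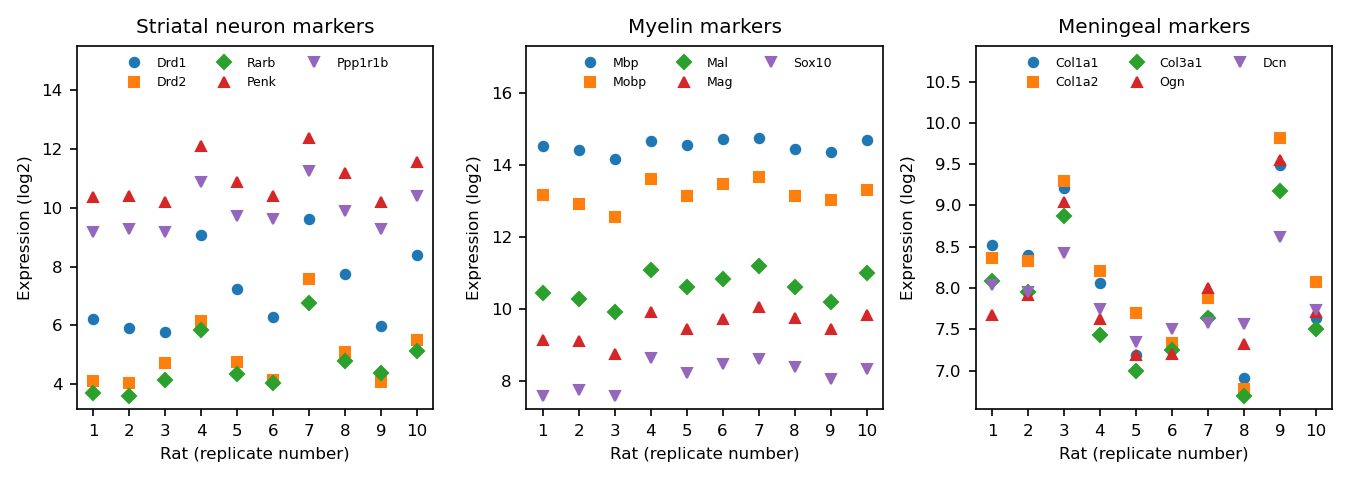
Expression (log2) of 5 striatal, 5 myelin and 5 meningeal marker genes in each of the 10 rats, 1 array per rat. Striatal genes were highest in rats 7 and 4, where Drd1 reached 9.60 and 9.07, and meningeal genes were highest in rats 9 and 3, where Col1a2 reached 9.82 and 9.29.

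The startle comparison asked which prefrontal transcripts vary with the size of the acoustic startle response. No gene passed the threshold, and those of smallest p are given first. Abcb8, a mitochondrial transporter of the ABC family, had a slope of 0.13 ± 0.02 (SE, n = 10), and the mitochondrial malic enzyme gene Me2 0.16 ± 0.04. Slopes of Ptk7, a Wnt pathway receptor gene, Paqr4 and the RNA polymerase II phosphatase gene Ctdp1 were 0.14 ± 0.03, 0.21 ± 0.05 and 0.15 ± 0.04. Gnptg, which takes part in tagging lysosomal enzymes, had a slope of -0.15 ± 0.03 (p = 0.000199, adjusted p = 0.808). The splicing regulator gene Celf2 had -0.14 ± 0.03, with 3 other probe sets of the same sign, and Myo10, a myosin of filopodia, had -0.19 ± 0.04. Acadsb, an enzyme of branched-chain amino acid breakdown, had -0.21 ± 0.05, and the histone demethylase gene Kdm2b -0.13 ± 0.03.

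GABA genes had negative slopes with startle in 12 of 14 measured members (median -0.05, camera adjusted p = 0.0395; adjusted p = 0.927 with an estimated correlation). The slopes were -0.14 ± 0.05 for Gad2, a GABA-synthesising enzyme gene, and -0.07 ± 0.03 and -0.12 ± 0.06 for the receptor subunit genes Gabra5 and Gabra4. After quantile normalization 6 of 14 members had positive slopes with a median of -0.02. The call ended without rat 2, 4, 7, 8 or 9, without the 3 rats of highest striatal score, and with the mean over all probe sets of a gene.

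Myelin and oligodendrocyte genes had positive slopes with startle in 19 of 19 members (median 0.10, camera adjusted p = 8.96e-06), and adjusted p = 0.927 with an estimated correlation. Fa2h, which makes hydroxylated myelin lipids, had 0.21 ± 0.08, and the regulators of myelin genes Sox10 and Myrf had 0.19 ± 0.11 and 0.16 ± 0.11. The median slope was 0.03 with the striatal marker score as a covariate, 0.06 without the 3 rats of highest striatal score, 0.03 without rat 7, 0.05 without rat 2 and 0.16 without rat 9, and 13 of 100 pairings of scores and rats gave a camera p as small. Striatal markers had positive slopes with startle in 11 of 12 members (median 0.12, camera adjusted p = 0.0317), among them Rarb at 0.42 ± 0.28, Rgs9 at 0.13 ± 0.09 and Drd2 at 0.36 ± 0.33. With an estimated correlation their adjusted p was 0.927. Their call ended without rat 1, 2 or 7, without the 3 rats of highest striatal score, with the 4 scores in 1 model and with the spike-in covariate, and the median turned to -0.04 without rat 7. After quantile normalization the adjusted p of the striatal list was 0.186.

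By limma, 0 of 15521 probe sets passed an adjusted p of 0.05 for startle, and 867 had an unadjusted p under 0.05 (199 with positive and 668 with negative slopes), where chance alone gives 776. The unmoderated Pearson test also gave 0, as did eBayes with trend and robust options. After quantile normalization the split turned to 556 positive and 318 negative, and the unadjusted count was 336 without rat 2, 1323 without rat 4 and 1318 without rat 6. Of 100 pairings of scores and rats, 86 called at least as many lists as the 3 called here.

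The locomotion comparison asked which transcripts vary with movement. Dnajc3, a chaperone of the endoplasmic reticulum, had 0.17 ± 0.04 (SE, n = 10; p = 0.00168, adjusted p = 1.00), and the nuclear pore gene Ranbp2 0.12 ± 0.03, with another probe set at -0.01. Slopes of Tmem43, the vesicle motor gene Myo5b and Ankrd6 were 0.22 ± 0.06, 0.11 ± 0.03 and 0.18 ± 0.05. On the negative side stood Klhl42 at -0.23 ± 0.06, the nuclear receptor coactivator gene Pelp1 at -0.14 ± 0.04, and Arhgdig at -0.09 ± 0.03. Tomm40l, of the mitochondrial import family, had -0.22 ± 0.06, and the tropomyosin gene Tpm3 -0.17 ± 0.05. Of 9 other Tpm3 probe sets, 6 had the opposite sign.

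Cytosolic ribosomal protein genes had positive slopes with locomotion in 23 of 23 members (median 0.04, camera adjusted p = 0.0317), with adjusted p = 0.927 under an estimated correlation. Rpl24, Rpl14 and Rpl27 had slopes of 0.09 ± 0.04, 0.06 ± 0.04 and 0.05 ± 0.04. The spike-in level varied with locomotion (r = 0.73, permutation p = 0.0152, adjusted 0.305 over 20 pairs; rho = 0.87, permutation p = 0.00183, adjusted 0.0366). Without the 2 farthest rats that r was 0.74. With the spike-in level as a covariate the median of the ribosomal list was 0.0037 and its adjusted p 0.756. The call ended without rat 1, 5, 7, 8 or 9, with ranks of the score, with the striatal covariate, and after quantile normalization (adjusted p = 0.0577, 19 of 23 positive). Nucb2, the nesfatin precursor gene, chosen after its values were seen, had 0.12 ± 0.03 (p = 0.00295), which made 1 gene of the feeding list past 0.05 when adjusted over the list alone and 0 over all genes.

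By limma 0 probe sets passed for locomotion, and 455 had an unadjusted p under 0.05 (359 positive, 96 negative). Both other tests gave 0. The split was 199 positive and 136 negative with arrays centred on their medians, and 182 and 280 after quantile normalization. Without rat 4 the unadjusted count was 1300 and without rat 10 it was 291. All 100 pairings called at least 1 list, as the actual one did.

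The sugar feeding comparison asked which transcripts vary with intake of a sweet food. Ostf1, a signalling adaptor gene, had a slope of 0.15 ± 0.03 (SE, n = 10; p = 0.000146, adjusted p = 1.00). Upf3b, of nonsense-mediated mRNA decay, had 0.26 ± 0.06, the dynein adaptor gene Bicd2 0.13 ± 0.03 and Mybpc3, a myosin-binding protein gene, 0.21 ± 0.05. Ap3s1, a subunit of an endosomal coat, had 0.27 ± 0.07, with another probe set near 0. Slopes were negative for Phlda1 (-0.11 ± 0.03), the sorting receptor gene Sort1 (-0.12 ± 0.04, with another probe set of opposite sign) and the Nogo receptor gene Rtn4r (-0.15 ± 0.04). They were also negative for Wdr20 (-0.14 ± 0.04) and Meaf6, of a histone acetyltransferase complex (-0.07 ± 0.02).

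Ribosomal protein genes had positive slopes with sugar feeding in 23 of 23 members (median 0.03, camera adjusted p = 0.0395; adjusted p = 0.927 with an estimated correlation). Rpl23, Rpl3 and Rpl24 had 0.04 ± 0.03, 0.05 ± 0.04 and 0.06 ± 0.05. The median turned to -0.04 with the 4 scores in 1 model. It was 0.02 with the spike-in level as a covariate, and 0.02 after quantile normalization with 22 of 23 members positive, both past no threshold. The call also ended with ranks, with the striatal covariate, without the 3 rats of highest striatal score, and without rat 1, 5, 7, 8 or 9.

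By limma 0 probe sets passed for sugar feeding, 330 had an unadjusted p under 0.05 (225 positive, 105 negative), and both other tests gave 0. After quantile normalization the split was 163 positive and 202 negative, and without rat 3 the unadjusted count was 1039. All 100 pairings called at least 1 list, as here.

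The prepulse inhibition comparison asked which transcripts vary with sensorimotor gating. Medag, named for a role in fat cell formation, had the smallest p for this score, with a slope of 0.29 ± 0.04 (SE, n = 10; p = 2.98e-05, adjusted p = 0.463). Slopes of 2 other Medag probe sets were 0.01 and 0.05, with unadjusted p of 0.681 and 0.534. The clock gene Per1, also induced by glucocorticoids and activity, had 0.33 ± 0.07 (p = 0.000423, adjusted p = 0.630), a 1.26-fold difference per SD. That slope leaned on rats 1 and 2, which had the lowest prepulse inhibition. Per1 was at 5.17 and 5.25 log2 in them and at 5.89 to 6.30 in all other rats. Nudt9, an ADP-ribose hydrolase gene, had 0.13 ± 0.03, the carbonyl reductase gene Cbr1 0.16 ± 0.04, and Khsrp, of mRNA decay, 0.29 ± 0.07, with 2 other probe sets of opposite sign. Negative slopes were those of Csnk2a2, a catalytic subunit gene of casein kinase 2 (-0.13 ± 0.03), the membrane skeleton gene Epb41l2 (-0.18 ± 0.04) and Ttyh1 (-0.19 ± 0.04). Of 3 other Csnk2a2 probe sets 1 was opposite and as large, at 0.13 (limma unadjusted p = 0.0338). Another Epb41l2 probe set was at -0.01 (limma unadjusted p = 0.753), and 3 others of Ttyh1 had the same sign. The synaptic adhesion gene Cadm1 had -0.12 ± 0.03. Upf3b had -0.26 ± 0.06, against 0.26 ± 0.06 with sugar feeding.

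**Figure D3:**
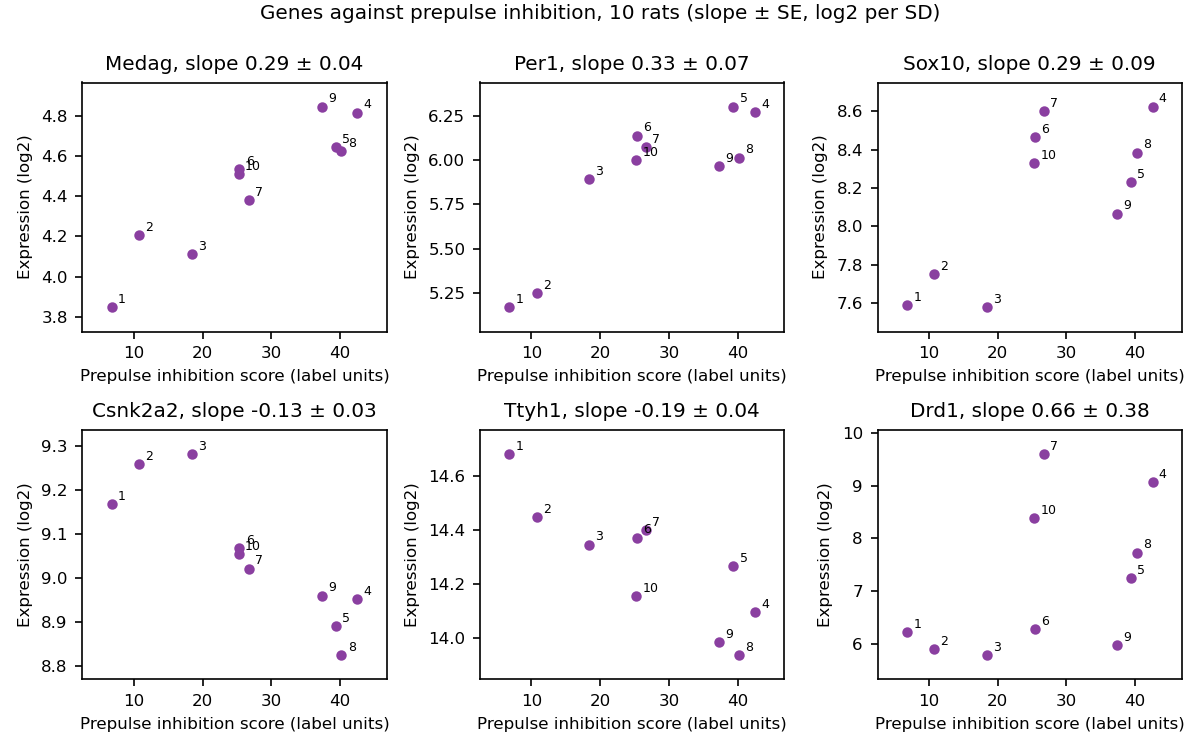
Expression (log2) of Medag, Per1, Sox10, Csnk2a2, Ttyh1 and Drd1 against the prepulse inhibition score in the units of the labels, with each point 1 rat numbered by replicate and slopes ± SE in log2 per SD. Slopes ran from -0.19 ± 0.04 for Ttyh1 to 0.66 ± 0.38 for Drd1, and none passed the adjusted threshold.

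Myelin and oligodendrocyte genes had positive slopes with prepulse inhibition in 19 of 19 members (median 0.13, camera adjusted p = 3.42e-07; adjusted p = 0.927 with an estimated correlation). Sox10 had 0.29 ± 0.09 (p = 0.00833), Fa2h 0.20 ± 0.08 and Mag 0.24 ± 0.11. The list stayed past the threshold without any single rat and after quantile normalization. Its median was 0.08 without rat 3 and 0.03 with the striatal score as a covariate, where the adjusted p was 0.00269. Striatal markers had positive slopes in 11 of 12 members (median 0.19, camera adjusted p = 0.0157; adjusted p = 0.927 with an estimated correlation). Rarb had 0.47 ± 0.27, Drd1 0.66 ± 0.38 and Ppp1r1b 0.32 ± 0.21. Their call ended without rat 2 or 4 and after quantile normalization (adjusted p = 0.0796). With the striatal covariate the adjusted p was 0.812, a loss that was built in, since that score is the mean of the same genes. Their median was 0.53 with the 4 scores in 1 model and 0.10 without the 3 rats of highest striatal score, both past the threshold. The striatal and myelin scores themselves were not past the threshold with prepulse inhibition: r was 0.39 (permutation p = 0.266, adjusted 0.824 over 20 pairs) and 0.46 (permutation p = 0.179, adjusted 0.224 over 10 pairs). Their rho was 0.58 (permutation p = 0.0888, adjusted 0.659) and 0.49 (permutation p = 0.153, adjusted 0.173), and r without the 2 farthest rats 0.14 and 0.52.

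Noradrenaline and acetylcholine receptor genes had positive slopes with prepulse inhibition in 8 of 10 members (median 0.08, camera adjusted p = 0.0260; adjusted p = 0.927 with an estimated correlation). The muscarinic receptor genes Chrm1 and Chrm3 had 0.11 ± 0.04 and 0.17 ± 0.08, and the adrenergic receptor gene Adra2a had 0.09 ± 0.05. Without rat 1 the adjusted p was 0.306 and the median 0.02, and after quantile normalization the adjusted p was 0.104. The call also ended without the filter on the mean (0.0807) and with the spike-in covariate (0.0820). Glucocorticoid and stress genes had positive slopes in 8 of 13 members, with a mean of 0.06 but a median of 0.01 (camera adjusted p = 0.0266; adjusted p = 0.927 with an estimated correlation). Beside Per1, Crhbp, which encodes a binding protein of corticotropin-releasing hormone, had 0.16 ± 0.05, and the stress-induced gene Ddit4 0.18 ± 0.06. Their call ended without rat 2, 4 or 9, with the striatal covariate (adjusted p = 0.0551), after quantile normalization (0.0796), without the filter (0.0540) and without the 3 rats of highest striatal score (0.0518). Per1 alone passed when adjusted over the list alone, in 3 lists (glucocorticoid 0.00387, clock 0.00447, immediate-early 0.00507), and 0 genes passed over all genes. The slope of Per1 leaned on rats 1 and 2, as given above.

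By limma 0 probe sets passed for prepulse inhibition, and 1150 had an unadjusted p under 0.05 (305 positive, 845 negative). Both other tests gave 0. Of the negative ones 47.7% had no gene symbol, against 14.1% of the positive ones and 23.7% of all tested. After quantile normalization the split was 609 positive and 520 negative, and without rat 1 the unadjusted count was 601. Of 100 pairings, 74 called at least as many lists as the 4 called here.

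In the panel of genes linked to cortical activity and behaviour, no gene passed for any score. Fos, an activity-induced transcription factor gene, had slopes of -0.34 ± 0.43 with startle, 0.64 ± 0.40 with locomotion, 0.37 ± 0.43 with sugar feeding and 0.13 ± 0.44 with prepulse inhibition. In the same order Egr1 had -0.13 ± 0.08, 0.16 ± 0.08, 0.07 ± 0.09 and -0.07 ± 0.09, and Arc -0.19 ± 0.28, 0.18 ± 0.28, 0.22 ± 0.28 and 0.17 ± 0.28. Drd1 had 0.32 ± 0.43, 0.21 ± 0.43, 0.12 ± 0.44 and 0.66 ± 0.38, and Drd2 0.36 ± 0.33, 0.23 ± 0.35, 0.37 ± 0.33 and 0.37 ± 0.33. The serotonin receptor gene Htr2a had -0.14 ± 0.11, -0.04 ± 0.12, -0.15 ± 0.11 and -0.03 ± 0.12, and another Htr2a probe set -0.06, -0.06, -0.10 and 0.0024. The glutamate receptor gene Grin2a had slopes from -0.07 ± 0.05 to -0.02 ± 0.06. Another Grin2a probe set had -0.33 with startle (limma unadjusted p = 0.0265), 0.06 with locomotion, -0.09 with sugar feeding and -0.13 with prepulse inhibition.

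Slopes of Gad1 lay between -0.03 ± 0.06 and 0.08 ± 0.05, of the parvalbumin gene Pvalb between -0.07 ± 0.05 and 0.05 ± 0.05, of the glucocorticoid receptor gene Nr3c1 between -0.03 ± 0.05 and 0.01 ± 0.05, and of Crh between -0.03 ± 0.04 and 0.06 ± 0.03. After quantile normalization the sign turned for Gad1 with startle and prepulse inhibition, Pvalb with startle, and Nr3c1 with locomotion and sugar feeding, each at a slope under 0.04.

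Of the 25 lists tested, 19 passed for no behaviour. The closest were heat shock genes with locomotion (median 0.02, 13 of 15 positive, adjusted p = 0.0680; after quantile normalization 8 of 15 positive with a median of 0.0030) and interneuron genes with sugar feeding (median -0.02, 9 of 12 negative, 0.0706). The lowest adjusted p of the other neuronal lists were 0.114 for glutamate receptors and transporters with startle (median -0.05, 17 of 24 negative, and -0.01 after quantile normalization) and 0.134 for synaptic vesicle genes with startle (median -0.02, and 0.02 after quantile normalization). Dopamine signalling had 0.153 with sugar feeding (median 0.10), superficial layer markers 0.153 with locomotion (-0.02), opioid and endocannabinoid genes 0.317 with sugar feeding (0.04), schizophrenia candidates 0.439 with prepulse inhibition (-0.03, and -0.0061 after quantile normalization), and deep layer markers 0.582 with sugar feeding (0.04).

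Among glia and other cells the lowest adjusted p was 0.121 for astrocyte markers with sugar feeding (median 0.04, 17 of 18 positive, and 0.02 after quantile normalization). It was 0.141 for meningeal and 0.143 for microglial markers with startle (0.06 and 0.04), 0.201 for oligodendrocyte precursor markers with sugar feeding (0.06), 0.261 for endothelial and 0.369 for olfactory bulb markers with prepulse inhibition (-0.04 and 0.04). Clock genes had 0.153 with sugar feeding (-0.02), immediate-early genes 0.176 with locomotion (0.07, 15 of 17 positive), oxidative phosphorylation genes 0.275 with sugar feeding (0.02, and 0.0062 after quantile normalization) and feeding genes 0.528 with locomotion (0.03). Serotonin signalling, blood and choroid plexus lists had 4, 2 and 2 measured members and were not tested.

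The 9 list calls, 3 with startle, 1 with locomotion, 1 with sugar feeding and 4 with prepulse inhibition, were calls of camera at its preset correlation. With an estimated correlation, with fry and with fry's mixed test 0 lists passed. Differences between behaviours in these slopes were not tested. The calls with startle and with prepulse inhibition are not separate results. Across probe sets the slopes with these scores had r = 0.74, and all 196 probe sets with a limma unadjusted p under 0.05 for both had the same sign. List members also varied together, with a median r between pairs of 0.890 for myelin and 0.881 for striatal genes. Members of 1 sign are therefore not separate observations.

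**Figure D4:**
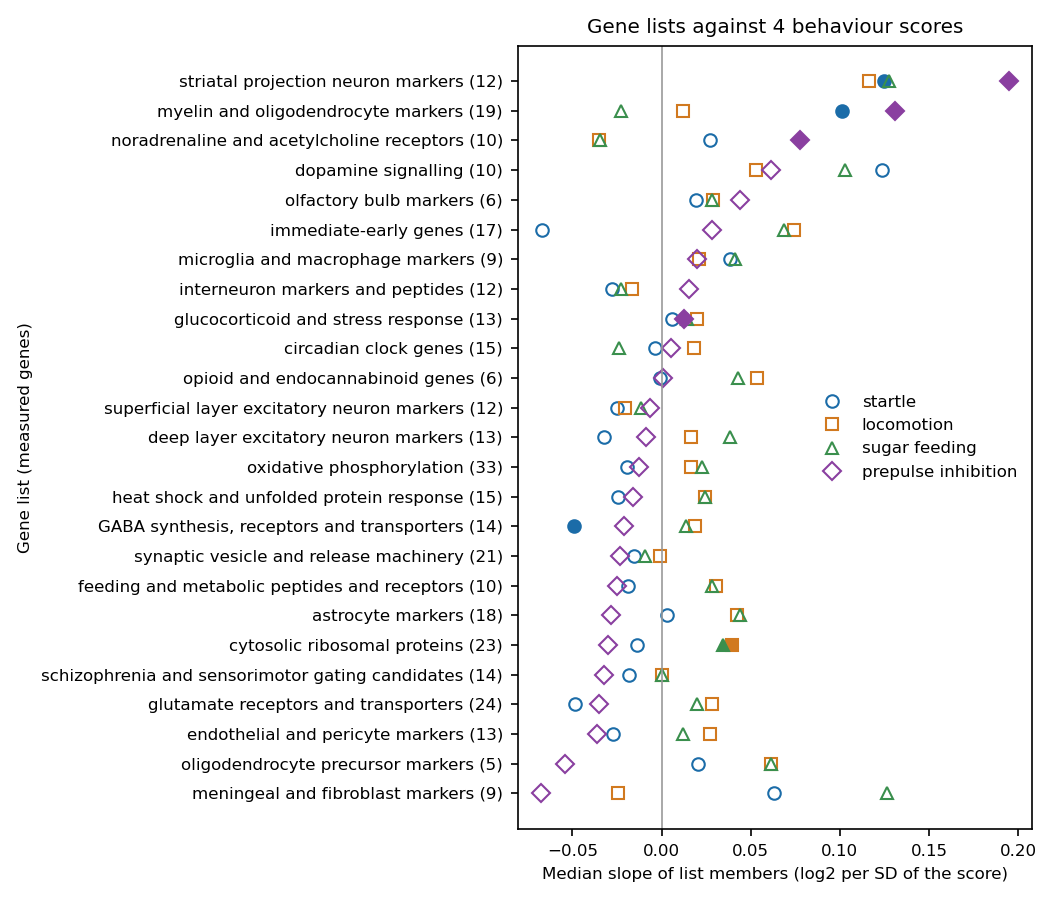
Median slope of the members of each of the 25 lists (log2 per SD of the score) with the 4 behaviours, with the number of measured genes in parentheses and filled symbols for the 9 list calls of camera at its preset correlation. The 9 medians run from -0.05 for GABA genes with startle to 0.19 for striatal markers with prepulse inhibition, and 0 lists passed with an estimated correlation.

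The plus maze score, known for 7 rats, was a secondary comparison. Zfp386, a zinc finger gene, had a slope of -0.37 ± 0.04, Ap3s1 -0.30 ± 0.04 and the makorin gene Mkrn2 -0.33 ± 0.05. Pank4, of the pantothenate kinase family, had 0.23 ± 0.04, the phospholipase gene Pla2g6 0.23 ± 0.04 and the zinc finger gene Zfp612 0.20 ± 0.04, with another probe set of opposite sign. All had a limma adjusted p of 0.558, and 0 probe sets passed by limma or by either other test, with 1078 at an unadjusted p under 0.05 (187 positive, 891 negative). Rat 5 had a score of 60.3 against at most 20.2 in the others. Without rat 5 the unadjusted count was 358, and after quantile normalization the split was 223 and 476.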

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

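The tests of striatal tissue and of RNA integrity for the striatal genes were chosen after the values were seen, as were the genes Pde10a, Penk, Foxp1, Foxp2 and Meis2. The measures below stand out because 1 rat lies far from the other rats, by the ratio of its gap from the nearest rat to the whole range (Dixon's test). Of 110 measures tested, 13 stood out, and chance marks about 1 in 20 groups.

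The plus maze score stood out for rat 5, at 60.3 against 20.2 for the next rat (ratio 0.665). Genes named for that score stood out through the same rat: Pank4 at 5.73 against 5.18 log2 (0.816), Pla2g6 at 5.75 against 5.41 (0.471), Zfp612 at 6.43 against 5.96 (0.771) and, on the low side, Zfp386 at 6.69 against 7.49 (0.638). These genes were picked for their relation to a score that rat 5 dominates.

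In rat 10 the activity-induced genes Fos and Egr1 were low, Fos at 4.91 against 7.42 log2 (ratio 0.528) and Egr1 at 11.38 against 11.98 (0.526). Rat 1 was low for the score of noradrenaline and acetylcholine receptor genes, at -0.22 against -0.03 (0.578), and for Rtn4r, at 8.43 against 8.77 log2 (0.495). Rat 4 was low for Tpm3, at 5.87 against 6.36 (0.589). Rat 7 was high for the striatal gene Rgs9, at 5.06 against 4.32 (0.720), and low for Acadsb, at 4.96 against 5.46 (0.543), and for Htr2a, at 7.09 against 7.87 (0.566).

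Some striatal projection neuron genes differed several-fold between rats, and the striatal score was highest in rats 7, 4 and 10. Array-wide scaling left in the deposited values was argued against by array medians of 3.91 to 4.02 and upper quartiles of 8.13 to 8.25 log2. These differed little beside striatal scores of -0.48 to 1.20. Quantile normalization left the SD of the striatal score at 1.02 times its value, and at no less than 1.01 times without any single rat. With arrays so alike that test could hardly have come out otherwise, so it adds no support. A candidate explanation is striatal tissue in some dissected pieces, which the labels' description of Fr1 and Fr2 does not name. It stays open, since the median correlation between pairs of members, 0.881, measures the shared variation to be explained. That correlation was as high for myelin genes (0.890). The abundant members Pde10a (mean 12.16 log2) and Penk (10.96 log2) spanned 2.62-fold and 4.53-fold, and 1.82-fold and 3.78-fold without rat 7. Foxp1, Foxp2 and Meis2, which are also expressed in cortex, spanned 1.41-fold, 2.17-fold and 1.46-fold. RNA integrity stays open, as the score kept 0.976 of its SD after regression on the 3-prime and 5-prime difference but as little as 0.716 without 1 of the rats, while rats 7 and 4, both with high scores, had the highest and the lowest difference (1.46 and 1.14 log2), which goes against a common cause. The striatal score passed the adjusted threshold with none of the 4 main behaviours (adjusted permutation p = 0.824 for each r). Other biological explanations were not tested, since the labels put all rats in 1 group.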

How the results depend on the processing

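The fits with the striatal score, the spike-in level or without rats 4, 7 and 10, and both scalings for lists, were chosen after seeing the data. The count of 0 probe sets past an adjusted p of 0.05 held for all 5 scores under every alternative run, except that 1 probe set without a symbol passed for locomotion without the 3 rats of highest striatal score (slope 0.62 ± 0.05, adjusted p = 0.0275, against 0.13 with all rats). Of 114 named slopes, 0 passed under any alternative, and 93 of 2839 alternative values changed sign, in 40 slopes. Correlations between behaviours and those with components stayed on the same side of the threshold. Signal over background limits what was tested, since probe sets with a mean log2 under 3.99 were left out of the reported fits.

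The number of list calls, 9 as reported, was 0 with an estimated correlation (0 for each of the 4 behaviours), 16 without the filter (startle 6, locomotion 2, sugar feeding 5), 28 with the 4 scores in 1 model (9, 7 and 6), and 15 without the 3 rats (locomotion 4, sugar feeding 4). It was 4 after quantile normalization (locomotion 0, prepulse inhibition 1), where 3 of the 9 calls were kept. Sugar feeding had 3 with the mean over probe sets, 2 with ranks and 2 with arrays centred on their medians, and locomotion had 2 with the striatal covariate. Of the 9 calls, 7 were kept without the filter, 8 with the mean over probe sets, 7 with the 4 scores in 1 model, 7 with ranks, 4 with the striatal covariate, 5 with the spike-in covariate, 5 without the 3 rats and 9 with centring. The loss of both striatal calls with the striatal covariate was built in, since that score is the mean of the same genes.

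Leaving out 1 rat gave 8 (rat 5 or 9) to 19 (rat 1) calls in all, 2 to 8 for startle (8 without rat 1), 0 to 4 for locomotion, 1 to 6 for sugar feeding and 3 to 6 for prepulse inhibition. Medians reversed for ribosomal genes with sugar feeding in the model of 4 scores (-0.036) and for striatal genes with startle with the striatal covariate (-0.0031), where the score is built from the same genes, and without rat 7 (-0.038, in a range of -0.038 to 0.19). With the 4 scores in 1 model medians grew to 0.12 for receptor and 0.07 for stress genes with prepulse inhibition, -0.10 for GABA genes with startle and 0.08 for ribosomal genes with locomotion. Median slopes without 1 rat ran from -0.076 to -0.017 for GABA genes and 0.034 to 0.16 for myelin genes with startle, 0.017 to 0.055 and 0.012 to 0.070 for ribosomal genes with locomotion and sugar feeding, and, with prepulse inhibition, 0.083 to 0.17 for myelin, 0.096 to 0.27 for striatal, 0.024 to 0.090 for receptor and 0.0031 to 0.047 for stress genes. Without 1 rat the unadjusted counts ran from 336 (without rat 2) to 1323 (without rat 4) for startle, 291 (rat 10) to 1300 (rat 4) for locomotion, 284 (rat 1) to 1039 (rat 3) for sugar feeding, 601 (rat 1) to 1424 (rat 5) for prepulse inhibition and 358 (rat 5) to 1363 (rat 7) for the plus maze score. Over the other alternatives the lowest was 321 for startle (4 scores in 1 model), 314 for the plus maze score (ranks) and, in the upper 25% with fewer probe sets tested, 191, 142 and 555 for locomotion, sugar feeding and prepulse inhibition. The highest was 1329 for locomotion (without the 3 rats), and 1516 and 1999 for prepulse inhibition and the plus maze score without the filter. Apart from that covariate, the cause was not tested.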

Other observations

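The tests of myelin genes against a covariate and against astrocyte genes, that of unnamed probe sets after quantile normalization, and those of the number of unnamed probe sets, with a bound of 0.8, were chosen after the result was seen, as were the genes named here outside the rule. Some activity-induced genes differed widely between rats and others did not. Jun, Homer1, Bdnf, Sik1, Egr4, Dusp6 and Nr4a3 spanned 1.37-fold to 1.80-fold. Fos spanned 26.9-fold, Arc 6.68-fold, Dusp1 3.85-fold, Nr4a1 3.79-fold and Junb 3.50-fold, and Egr1, at a mean of 12.11 log2, 2.19-fold. Without rat 10, which had the lowest values of both, Fos spanned 4.73-fold and Egr1 1.45-fold. Fos was highest in rats 8, 3 and 4, at 9.66, 9.60 and 9.59 log2, and Arc in rats 3, 8 and 4, at 11.18, 10.83 and 10.30. The growth factor gene Igf2 spanned 5.55-fold and was highest in rats 9 and 3, as were the collagen genes. The haemoglobin gene Hbb spanned 1.88-fold.

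With prepulse inhibition, clock genes did not move one way. The clock-controlled gene Dbp had a slope of 0.21 ± 0.08 (unadjusted p = 0.0233) and Nr1d2 0.07 ± 0.03 (0.0497), in the direction of Per1, while Cry2 had -0.08 ± 0.03 (0.0313) and Bmal1 -0.09 ± 0.07. The glucocorticoid target Fkbp5 had -0.09 ± 0.05 (0.118), opposite to Per1.

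Random pairings of scores and rats gave results as large for each summary below, so chance cannot be excluded for any of them. For startle, 31 of 100 pairings had as many probe sets at an unadjusted p under 0.05 as the actual 867 (highest other 2214), and 86 as many lists as the actual 3 (highest other 13). For locomotion it was 76 for the 455 probe sets (highest other 2986) and 100 for the 1 list (highest other 12). For sugar feeding it was 86 for the 330 probe sets (highest other 1909) and 100 for the 1 list (highest other 12). For prepulse inhibition it was 16 for the 1150 probe sets (highest other 2490) and 74 for the 4 lists (highest other 12). For the plus maze score it was 36 for the 1078 probe sets (highest other 1937). Over the 4 behaviours together, 99 of 100 pairings called as many lists as the actual 9 (median other 19, highest other 36). For myelin genes with startle, 13 of 100 pairings gave a camera p as small. The cause of counts several times the actual one was not tested.

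Myelin genes had positive slopes with prepulse inhibition, and 11 of 100 pairings gave the list a camera p as small (actual -log10 p 8.47, highest other 24.0), so chance cannot be excluded. A fall in neurons with a rise in all glia stays open, since the myelin score minus the astrocyte score, built from the score that prompted the test, was not related to prepulse inhibition past the adjusted threshold (r = 0.69, permutation p = 0.0314, adjusted 0.0607 over 10 pairs; rho = 0.65, permutation p = 0.0491, adjusted 0.0981; r = 0.51 without the 2 farthest rats, permutation p = 0.20, n = 8). Astrocyte markers had negative slopes with prepulse inhibition in 15 of 18 members (median -0.03, camera adjusted p = 0.317; 10 of 18 after quantile normalization) and oligodendrocyte precursor markers in 3 of 5 (median -0.05, 0.583), which goes against a rise in all glia but passed no threshold, while microglial markers were positive in 6 of 9 (median 0.02, 0.770). Striatum or white matter in the dissected pieces stays open too. The median slope with the striatal score as a covariate was 0.259 of that without, and at most 0.480 without any single rat. Without the 3 rats of highest striatal score the median kept 0.824 of its value. Camera at its preset correlation called the list in both fits (adjusted p = 0.00269 and 1.19e-06). Those calls do not weigh against the explanation, since the list did not pass with an estimated correlation (adjusted p = 0.927, all rats, no covariate). The striatal score was built from striatal neuron genes, so it does not measure white matter alone. A relation of myelin to prepulse inhibition itself also stays open.

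Probe sets without a gene symbol made up 403 of the 845 with negative slopes and an unadjusted p under 0.05 for prepulse inhibition, a count that 2 of 100 pairings reached (highest other 484), but 16 of 100 reached it when the largest count over 4 behaviours and both signs was taken, so chance cannot be excluded, and it was 140, 210 and 235 without rat 1, 2 or 4. Dim signal was argued against by an unnamed share 1.81 times that of all probe sets in the upper 25% by mean. RNA integrity as the whole cause was argued against by its covariate, but only by the bound on number, chosen after the result was seen. With that covariate the unnamed ones, 405, kept 1.00 times their number and at least 0.848 times without any single rat. The named ones rose from 442 to 608, and the unnamed share was 39.98%, just short of the bound of 40% set before. The amount of labelled RNA, array-wide scaling and striatum or white matter stay open: the share was 48.5% with the spike-in covariate and 54.8% after quantile normalization, but a share above 40% alone was the wrong bound, since the unnamed ones fell from 403 to 215 of 443 and to 285 of 520, and with the striatal covariate the share was 39.1% (213 of 545). Across rats the mean level of unnamed probe sets and prepulse inhibition had r = -0.66 (permutation p = 0.0364, adjusted 0.0607 over 10 pairs) and rho = -0.56 (permutation p = 0.0948, adjusted 0.135), which rested on the 2 farthest rats, since r was -0.04 without them. The same level and the striatal score had r = -0.74 (permutation p = 0.0161, adjusted 0.0403) and rho = -0.73 (permutation p = 0.0203, adjusted 0.0508), with r = -0.77 without the 2 farthest rats, and the same level and the spike-in level had r = 0.64 (permutation p = 0.0483, adjusted 0.0690) and rho = 0.49 (permutation p = 0.156, adjusted 0.173), with r = 0.25 without the 2 farthest.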
